A study of Mus musculus with 36 samples.

How the data were processed

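Liver mRNA of C57BL/6J male mice was measured on single-colour Illumina bead arrays, on which each probe is carried by many beads and read as the mean brightness of those beads. Per the labels, the mice were 12 weeks old and had been kept for 4 weeks in 12 hours of light and 12 hours of darkness before sampling. Livers were frozen, total RNA was isolated with a column kit, and 100 ng per sample was amplified and labelled with biotin. The 36 arrays cover 12 time points at 4-hour steps, from Zeitgeber time 4 (ZT04, 4 hours after lights on) to ZT48, with 3 arrays numbered 1 to 3 at each. The labels do not say that the 3 replicates of a time point came from separate animals, nor whether lights were kept on and off during sampling, so p-values measure only the spread between these arrays, which may be technical. Hours are therefore given as hours of the entrainment cycle.

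The intensity of each probe is the authors' deposited mean bead signal of 1 array, linear, never below 0 and with no background subtraction or normalization between arrays that the values show. Each probe also has a detection score between 0 and 1, deposited by the authors per the file headers, which rises with brightness and was read as 1 minus a detection p-value against negative controls. The number of beads and the spread between beads are given beside it per the file headers, and the scanner software is not given in the sources used here. The authors also deposited a table of processed values for the same arrays. Its values run from -8.44 to 17.2 with column medians from 5.45 to 5.76, and all 36 of its columns match the probe ranks of their own array best, at a rank correlation of 1, so the scale was read as log2 of a background-reduced and normalized signal, as the values of the authors' table show. How the authors normalized them is not given in the sources used here, and whether values were centred stays unknown. That table served only as an alternative.

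Each array holds 46628 probes, of which 559 control probes or probes of other organisms were left out after normalization. Probes carry identifiers and no gene names. A zero-padded number inside an identifier was read as a gene identifier and looked up in a reference table of gene names (assembly GRCm38.p6, used for names only). Among the 11857 identifiers of this form 82.6% of the numbers were gene identifiers in the table, against 38.1% when the number was shifted by up to 50. For numbers in the other forms the shares were 8.53% and 8.46%, and these were not used. RIKEN clone names that the table lists as genes named 981 more probes. In all 10777 probes were named for 8678 genes and 35851 were left unnamed, Arntl, Per1, Per2, Per3, Cry1, Cry2, Nr1d1 and Dbp among the genes not analysed here. The names were checked on levels. Of hepatocyte markers, 5 genes had a median level of 15.93 (log2), ribosomal proteins 14.25 and oxidative phosphorylation 13.73, each above 100% of 10000 random lists of named genes, while pancreas markers lay at 8.38, above 45.4% of random lists. Pairs of probes for the same gene had a median correlation across arrays of 0.368 (436 pairs), against -0.0132 for random pairs.

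Signals were background-corrected, quantile-normalized and put on the log2 scale with the neqc function of limma (version 3.58.1, R 4.3.3), using the detection scores in place of control probes and an offset of 16. The background correction leaves a floor near 8.4 on this scale, so folds of dim genes are understated. A probe was tested if its detection score was over 0.99 on at least 3 arrays, which left 13018 probes. A gene with several tested probes (436 genes) was represented by the probe with the highest mean signal. This gave 12536 features, 3719 genes with a symbol and 8817 unnamed probes. Of the 436 genes, 210 were called for a 24-hour rhythm at the brightest probe, 104 of them at every tested probe, and 77 of these with all peaks within 3 hours. Figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

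Between 10045 and 12219 probes were detected per array, the median signal ran from 117 to 159.4, and a probe was the mean of a median of 32 to 35 beads. No 2 arrays held identical signals. Precision is limited by the number of arrays, and a fold near the floor cannot be measured.

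All tests used limma with moderated statistics and Benjamini-Hochberg adjustment, a feature being called at an adjusted p under 0.05. A 24-hour rhythm was a moderated F test of the cosine and sine of a 24-hour period over all 36 arrays. The amplitude is the distance on the log2 scale from the mean to the fitted peak, the peak-to-trough fold follows from it, and the peak hour is that of the fitted wave. A change with time of any shape was an F test over the 12 time points. A 12-hour component was an F test of 12-hour terms beside the 24-hour terms. The light phase was compared with the dark phase as the mean of ZT04, ZT08, ZT28 and ZT32 minus the mean of ZT16, ZT20, ZT40 and ZT44. The second cycle (ZT28 to ZT48) was compared with the first (ZT04 to ZT24) with hour of day in the model, and a last F test asked whether the 24-hour wave differed between the cycles. Gene lists were tested with Fisher's exact test (one-sided), fry and camera. Camera used a preset correlation of 0.01, with the estimated correlation beside it. The lists, the comparisons and the rule for named genes were fixed before the data were examined.

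Genes named by that rule were every tested member of the clock lists, the 10 largest 24-hour amplitudes among genes whose peaks in the separate cycles lay within 3 hours, the 10 highest and 10 lowest in the light phase with the same sign in each cycle, the 10 largest 12-hour amplitudes, the 5 highest and 5 lowest in the second cycle, the 5 largest differences of the wave between cycles, up to 4 called members of each list by amplitude, and members of marker lists that changed. Clone names were counted and not named, and some genes are not reported here. Named outside this rule, after their values had been seen, were the list members Hsp90ab1, Hspe1, Hspd1, Acaca, Fdps, Gstm1, Cyp3a11, Slc10a1, Slco1a1, Igf1, Tdo2, Cish, Sgk1 and Apoa4, the interferon genes with Igtp, the genes high at hour 8 and those that differ between ZT48 and ZT24.

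On simulated data with the spread of these arrays and a set of features changed by known sizes, the 24-hour test recovered 86.6% of features with an amplitude of 0.25, 100% at 0.5 and 100% at 1, with 1 false call among 12536 features and a median peak error of 0.129 hours at the smallest size. The comparison of light with dark recovered 71.6%, 92.5% and 98.5% at those sizes, with 0 false calls. With the replicate number as a block in the fit, false calls rose to 6 for the 24-hour test and 13 for light with dark. The simulated spread was that between arrays, so these false calls do not cover time points that differ as a whole.

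Replicate numbers were checked for pairing. Deviations from the time-point means of arrays with the same number correlated at 0.279 or more in all 198 pairs (mean 0.726), against a mean of -0.29 between different numbers, so the numbers pair the arrays. The median SD within a time point was 0.0884 over 3 replicates and 0.0491 between replicates 2 and 3, and 9536 features (76.1%) differed between the numbers. The source of this pairing is not in the labels. Counts with the replicate number as a block are given for each comparison, and for lists of the 24-hour rhythm where they differ.

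Alternatives were no background correction, median scaling, cyclic loess, the authors' table, no filter, detection on all 36 arrays, all probes as separate features, the replicate block, array weights, another variance prior, an adjusted p under 0.01, each array left out in turn, each cycle alone, a fold of at least 1.5, ranks, and all 12 time points in the comparison of light with dark. Chosen after seeing the data were the means of the 12 time points as units, the fits without ZT48 with and without the block, replicate 1 alone, and replicates 2 and 3 alone. The slide as a block was planned and not run, since the files used here carry no slide identifier.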

Results

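Messenger RNA was measured in mouse liver over 2 daily cycles. Each of the 12 time points from ZT04 to ZT48 had 3 arrays, 36 in all, and each array detected between 10045 and 12219 probes. Levels are log2 signals, errors are standard errors of fitted values or standard deviations (SD) of the 3 arrays of a time point, and adjusted p-values are those of limma.

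Gpcpd1, Mt1, Ppp1r3b and Eif4ebp3 had the largest 24-hour amplitudes among named genes. Gpcpd1, which encodes a phosphodiesterase of glycerophosphocholine, had an amplitude of 1.87 ± 0.13, a 13.3-fold difference between peak and trough, and peaked at hour 9.75 (adjusted p = 1.04e-12). Its level was 13.09 ± 0.13 (SD, n = 3) at ZT12 and 9.63 ± 0.06 at ZT20. The metallothionein Mt1 followed at 9.23-fold with a peak at hour 9.53. Ppp1r3b, which directs protein phosphatase 1 to glycogen, varied 7.36-fold with a later peak at hour 18.3. Eif4ebp3, a repressor of translation initiation, reached 7.34-fold at hour 15.3. Near the end of the light phase peaked Coq10b, a coenzyme Q binding protein (6.6-fold, hour 11.6), and the uridine phosphorylase gene Upp2 (6.09-fold, hour 11.9). Ddc, the aromatic amino acid decarboxylase, varied 5.12-fold with a peak at hour 22.4. Arrdc3, an arrestin-domain gene, varied 4.67-fold with a peak at hour 6.27. In all 10 genes of largest amplitude, which also include Por and Hspb1, the call held when the 12 time-point means were the units (adjusted p from 0.000174 for Por to 0.0122 for Mt1, by limma).

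**Figure D1:**
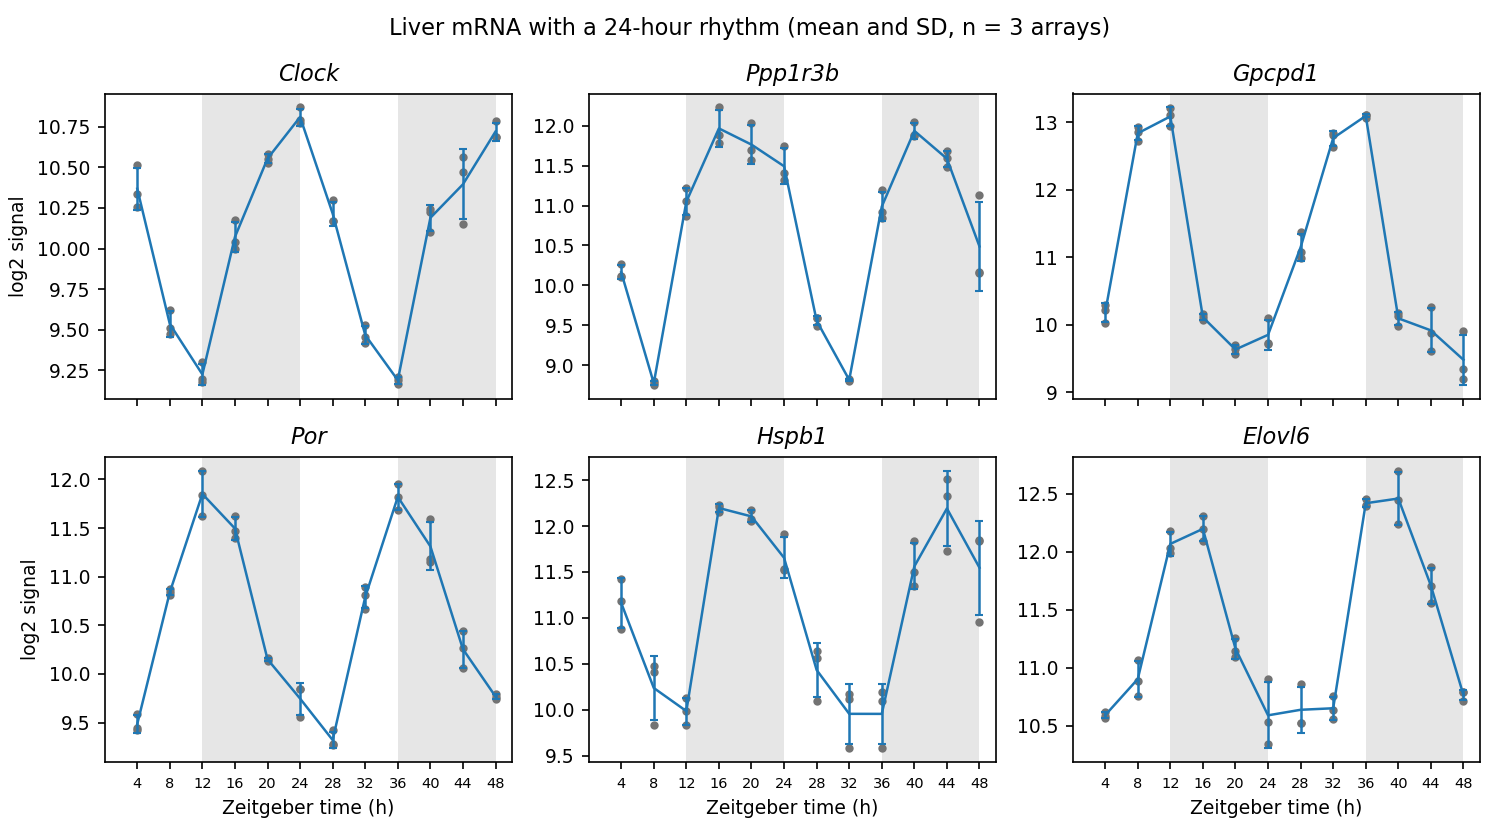
Log2 signal of 6 genes against Zeitgeber time in hours, where points are single arrays, lines join the means of 3 arrays, bars are SD and grey marks the dark phase of the entrainment cycle. Clock peaks near hour 22.8, Ppp1r3b near 18.3, Gpcpd1 near 9.75, Por near 13.3, Hspb1 near 20.5 and Elovl6 near 15, in both cycles.

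Of 4 measured members of the activator arm of the clock 3 passed, 3 adjusted over the list alone, Clock and Npas2 among them. Clock, a core activator of the circadian oscillator, had an amplitude of 0.75 ± 0.04 (2.81-fold) and peaked at hour 22.8 (adjusted p = 2.97e-16). Its level went from 10.81 ± 0.05 (SD, n = 3) at ZT24 to 9.23 ± 0.07 at ZT12. Npas2, a paralog of Clock, passed at the floor of the measurement, with a level of 8.38 and an amplitude of 0.05 ± 0.01 at hour 0.783. Rora had an amplitude of 0.07 ± 0.08 over all arrays (adjusted p = 0.742) and of 0.2 without the 3 arrays of ZT48 (adjusted p = 0.00741). Of the repressor arm 3 of 14 members were measured. Csnk1d, a kinase that phosphorylates PER proteins, passed with an amplitude of 0.12 ± 0.03 at hour 7.58, while Csnk1e (0.01 ± 0.01) and Nr1d2 (0.1 ± 0.06) did not. A second, dimmer probe of Nr1d2 passed (amplitude 0.05, adjusted p = 0.00741) with a peak at hour 8.68 against 18.9, so Nr1d2 is uncertain. All 3 measured genes downstream of the clock were rhythmic within 0.28 hours of their mean peak at hour 13.1. Por, the electron donor of microsomal cytochrome P450 enzymes, varied 5.26-fold. Cyp2a5, a coumarin hydroxylase, varied 2.93-fold and its near-identical paralog Cyp2a4 varied 3.03-fold. A second probe of Cyp2a5 had an amplitude of 1.46 against 0.78, with a peak at hour 12.7. Probes may bind both genes, so these folds are uncertain.

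Heat shock chaperones peaked in the dark phase. Of 9 measured heat shock chaperones 7 were rhythmic, 7 also when adjusted over the list alone, and all of these peaked within 1.97 hours of hour 19.6. The small heat shock gene Hspb1 varied 4.89-fold (hour 20.5), Chordc1 2.44-fold, Fkbp4, a cochaperone of steroid receptors, 2.28-fold and Hsp90ab1 1.78-fold. Hsp90aa1 (2.92-fold, adjusted p = 0.0121) had the largest standard error of the list. Hspe1 (adjusted p = 0.181) and Hspd1 (adjusted p = 0.296), the mitochondrial chaperonin pair, did not pass, and with the replicate block both did (adjusted p = 0.000756 for Hspe1 and 0.000897 for Hspd1), 9 of the list in all. Hspd1 also passed on time-point means (adjusted p = 0.0179). Cirbp, an RNA-binding protein induced by mild cold, peaked nearly opposite at hour 6.98 with an amplitude of 0.11 ± 0.01, near the floor, and with the block Srsf5, the other cold-inducible gene measured, passed too (adjusted p = 4.23e-06, against 0.216). Of 6 endoplasmic reticulum chaperones and stress genes 3 passed, Ero1b with the largest amplitude (0.31 ± 0.09, hour 21.8), and 4 passed with the replicate block. Ero1b had an adjusted p of 0.193 on time-point means and of 0.292 in the authors' table.

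Genes of fatty acid and triglyceride synthesis peaked mainly in the dark phase, while those of cholesterol synthesis peaked at more varied hours. All 7 measured genes of fatty acid and triglyceride synthesis were rhythmic, 7 adjusted over the list alone and 4 on time-point means. Elovl6, which elongates fatty acids, varied 3.89-fold with a peak at hour 15 (adjusted p = 3.64e-13). Fasn, the fatty acid synthase, varied 2.36-fold at hour 17.9, Acly, which makes cytosolic acetyl-CoA, 2.06-fold at hour 19.6 and Acaca, the acetyl-CoA carboxylase, 1.49-fold at hour 16.5. Lpin2, a phosphatidate phosphatase, peaked earlier at hour 11.2 (adjusted p = 0.0512 on time-point means). Of 15 genes of cholesterol synthesis 10 passed, 10 adjusted over the list alone and 11 with the replicate block, with peaks spread over the day. Lss, the lanosterol synthase, varied 2.9-fold at hour 19.6 and Fdps 1.57-fold at hour 20.4. Hmgcs1, which makes a precursor early in the pathway, varied 2.1-fold with a peak at hour 0.969. Of 6 genes of fatty acid oxidation and ketogenesis 3 passed, with Acot3 at 3.19-fold (hour 13.9), Angptl4 at 2.07-fold (adjusted p = 0.0928 on time-point means) and the ketone body gene Bdh1 at 1.42-fold, and 4 passed with the block.

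Of 5 genes of glucose and glycogen handling 4 passed, and 5 did adjusted over the list alone or with the replicate block. Besides Ppp1r3b these were Slc37a4, the glucose-6-phosphate transporter (2.3-fold, hour 14.2), Foxo1 (1.18-fold, adjusted p = 0.121 on time-point means) and Pck1, the gluconeogenic carboxykinase (3.27-fold, hour 9.58, adjusted p = 0.0233). The amplitude of Pck1 had a standard error of 0.26, and on time-point means its adjusted p was 0.0683. Of 16 genes of xenobiotic metabolism 6 passed, 6 adjusted over the list alone and 9 with the block, among them the glutathione transferase genes Gstt2 (2.48-fold, hour 13.6), Gsta2 (2.14-fold, hour 12.2) and Gstm1 (1.28-fold, hour 6.13, adjusted p = 0.0929 on time-point means) and the monooxygenase Fmo5 (2.12-fold, hour 16.6). Cyp3a11 had an amplitude of 0.17 ± 0.09 and did not pass. Of 6 autophagy genes 3 passed, 3 adjusted over the list alone and 4 with the block. The 3 peaked early in the light phase, Sqstm1 1.39-fold at hour 3.83, Lamp2 1.36-fold at hour 2.54 and Atg12 1.28-fold at hour 1.33. Lamp2 did not pass in the authors' table (adjusted p = 0.174), nor did Atg12 (adjusted p = 0.105). The bile salt and drug exporter Abcc2 varied 1.55-fold, and Slc10a1 and Slco1a1, the other 2 of 3 bile acid genes measured, did not pass (adjusted p = 0.0928 and 0.179) and did with the block (adjusted p = 0.0234 and 0.00365).

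Of 5 genes of the cell cycle 3 passed, 3 adjusted over the list alone. Cdkn1a, an inhibitor of the cell cycle, peaked at hour 21.5 (1.67-fold) and Ccnd1, cyclin D1, at hour 12.4 (2.14-fold). The level of Cdkn1a was 8.67, near the floor, so its fold may be understated. The amplitude of Ccnd1 was 0.55, and 0.31 in the second cycle alone (adjusted p = 0.0879). Of 6 acute phase genes 4 passed and 5 did adjusted over the list alone, with Cebpb, a transcription factor of the liver, at 2.2-fold (hour 13.1), Stat3 at 1.6-fold (hour 2.12) and Saa2 at 1.57-fold. Stat3 (adjusted p = 0.0781) and Saa2 (adjusted p = 0.252) did not pass on time-point means. Of 4 genes that respond to glucocorticoids 3 passed, 3 adjusted over the list alone, Mt1 and Errfi1, a feedback inhibitor of the epidermal growth factor receptor (1.84-fold, hour 10.8), among them. Errfi1 had an adjusted p of 0.0893 without ZT48 and of 0.249 on time-point means, and in the first cycle alone its amplitude was 0.14 against 0.44. Of 4 genes of the insulin and growth hormone response Igfals, which carries insulin-like growth factors in blood, passed (1.37-fold, hour 18.1, amplitude 0.22 and 0.1 in the second cycle alone at adjusted p = 0.143), and Igf1 did only with the block (adjusted p = 0.0276, against 0.43). Of 4 immediate early genes Klf6 (1.31-fold, hour 4.63) and Junb (1.2-fold, hour 5.21) passed, and on time-point means they did not (adjusted p = 0.0538 for Klf6 and 0.232 for Junb). Tdo2, the 1 measured gene of NAD and heme metabolism, did not pass (adjusted p = 0.722).

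Few ribosomal protein genes and none of the hepatocyte markers passed, and the amplitudes of Rps19 and Trf differed between normalizations. Of 29 ribosomal protein genes 1 passed (Rps19, amplitude 0.04 ± 0.01), 0 adjusted over the list alone by limma and 7 with the block. In the authors' table the amplitude of Rps19 was 0.25 and it did not pass (adjusted p = 0.107). Of 22 genes of oxidative phosphorylation 3 passed, led by Sdhb at 1.3-fold, 2 adjusted over the list alone and 6 with the block. Sdhb had an amplitude of 0.19, and without ZT48 of 0.1 (adjusted p = 0.226), and did not pass on time-point means (adjusted p = 0.153). Of 12 ribosome biogenesis genes 7 passed, 7 adjusted over the list alone and 2 on time-point means, Pes1 1.24-fold and Fbl, the nucleolar methyltransferase, 1.41-fold. The list had a median level of 8.76, near the floor. Fbl had an amplitude of 0.25, and without ZT48 of 0.13 (adjusted p = 0.129), and did not pass on time-point means (adjusted p = 0.181). None of 5 hepatocyte markers passed in limma, the lowest adjusted p being 0.0757 for Trf, whose amplitude was 0.02 ± 0.01. Trf passed in the authors' table (amplitude 0.21, adjusted p = 0.017) and with array weights (adjusted p = 0.0117), and with the block 1 marker, Serpina1a, passed (adjusted p = 0.00223). The median level of these markers, 15.93, lay near the top of the measured range, so whether they are flat is uncertain. Of 5 Kupffer cell and macrophage markers 3 passed, 4 with the block, with fitted peaks within 0.692 hours of hour 10.7 and Lyz2, a lysozyme of myeloid cells, at 2.26-fold (adjusted p = 0.118 on time-point means, where 0 of the 5 passed). The level of Lyz2 was highest at ZT08 and ZT32, so its fitted peak is not the hour of its highest level. Of 5 endothelial markers 2 passed, 3 with the block, Fcgr2b 1.43-fold at hour 14.6. Of 5 stellate cell and fibroblast markers 3 passed, 4 with the block and 0 on time-point means, led by Reln at 1.29-fold (adjusted p = 0.161 in the authors' table). Spp1 (cholangiocytes, 1.67-fold, hour 4.59), Cd74 (antigen-presenting cells, 2.27-fold, hour 8.08), Hba-a1 (red blood cells, 1.54-fold, hour 23.4) and Slc1a2 (pericentral hepatocytes, 1.39-fold) passed too. On time-point means Cd74 (adjusted p = 0.244) and Hba-a1 (adjusted p = 0.247) did not pass, and Cd74 did not by ranks (adjusted p = 0.191). In the authors' table Hba-a1 (adjusted p = 0.137) and Slc1a2 (adjusted p = 0.21) did not pass, nor did Slc1a2 with median scaling (adjusted p = 0.309). Of 3 red blood cell markers 2 passed with the block. Of 4 periportal genes Pigr passed (1.25-fold, adjusted p = 0.0479, and 0.839 in the authors' table) and 0 did adjusted over the list alone. The pancreas gene Cela2a (1.07-fold) passed near the floor, and did not on time-point means (adjusted p = 0.0969). Members of the adipose list were not analysed here.

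**Figure D2:**
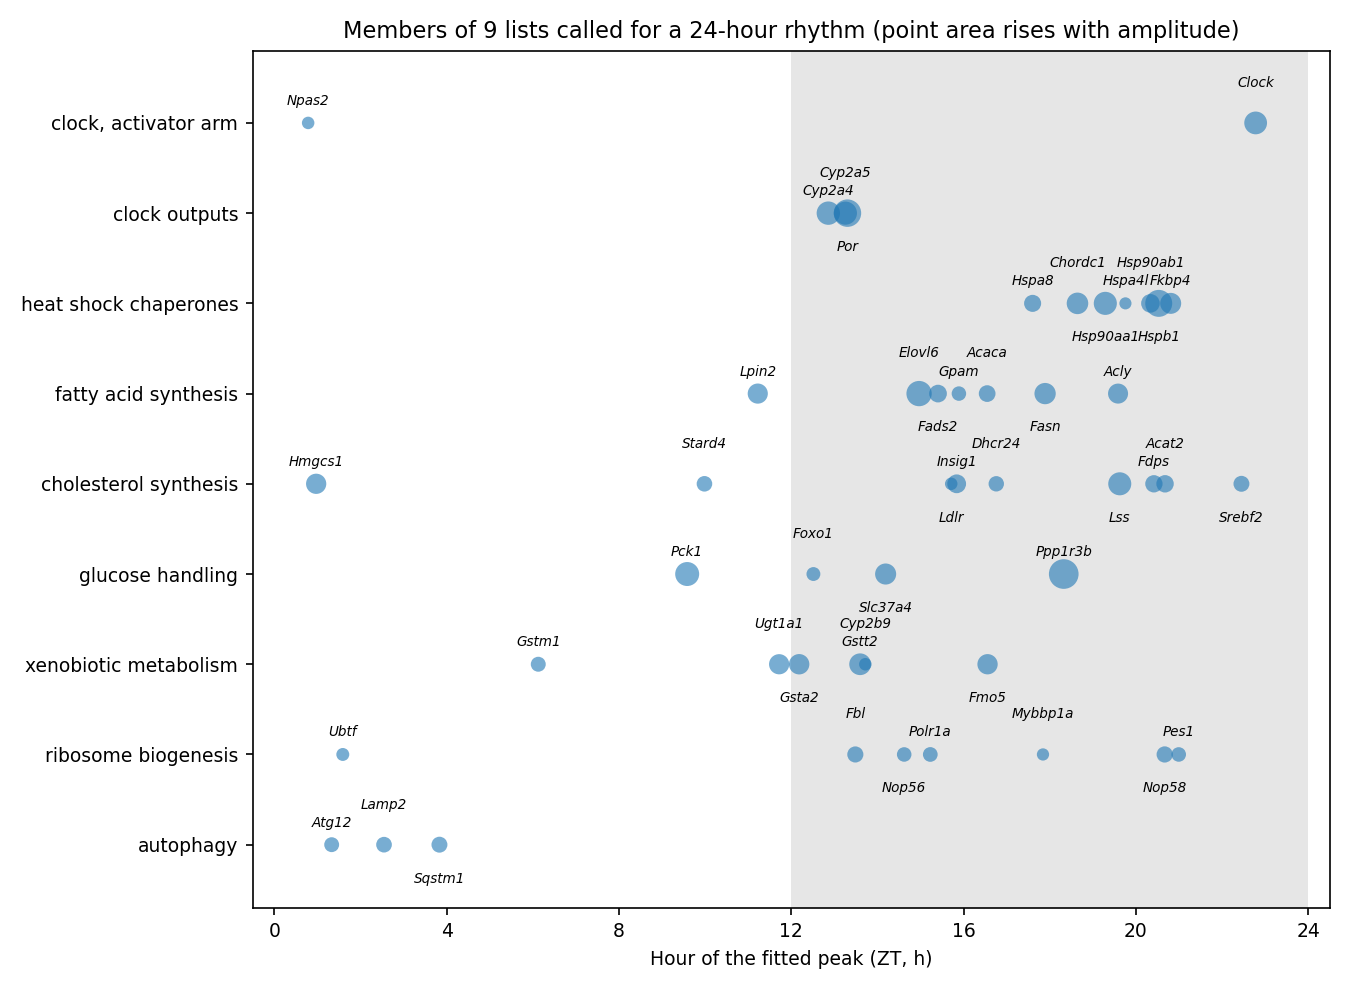
Hour of the fitted 24-hour peak (Zeitgeber time, hours) of called members of 9 gene lists, 1 point per gene with an area that rises with its amplitude; grey marks the dark phase. Heat shock chaperones lie around hour 19.6, the 3 autophagy genes between hours 1.33 and 3.83, and cholesterol synthesis is spread.

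In all 5694 of 12536 features (45.4%), 1660 of them named genes, had a 24-hour rhythm. Most were small, with a median peak-to-trough fold of 1.18 among those called, and 971 reached 1.5-fold, 300 2-fold and 47 4-fold. The peak hours from separate fits to the 2 cycles lay within 3 hours of one another in 90.5% of called features and in 43.4% of the others. The called features had been selected with both cycles, which favours such agreement. Of the 2977 features called in the first cycle alone, 85.8% peaked within 3 hours of that in the second, where chance gives 25%. Peaks fell between hours 0 and 12 for 53.8% of called features, and for 45.3% of those with at least 2-fold. The fullest 4-hour bin was from hour 20 to 24, with 1260 features, and the emptiest from hour 16 to 20, with 580. With median scaling 77.9% peaked between hours 0 and 12 and with the authors' values 69.3%. Over all features, called or not, the shares were 50.5% in the main fit, 74% with median scaling and 65.9% with the authors' values. These 2 scalings thus moved the features as a whole. With the replicate block 7789 were called. On time-point means 3311 features were called, 2965 of them among the 5694. Of all named genes 44.6% were called, and by Fisher's exact test 0 lists held a larger share at an adjusted p under 0.05. The lowest adjusted p was 0.112, for fatty acid and triglyceride synthesis, whose unadjusted p was 0.00351, and heat shock chaperones had an unadjusted p of 0.0473. Among changes of at least 1.5-fold 5 lists held a larger share, with adjusted p of 0.000693 for heat shock chaperones, 0.00114 for fatty acid synthesis, 0.00612 for genes downstream of the clock, 0.0067 for cholesterol synthesis and 0.0323 for glucose handling. The floor understates folds of dim genes, so this bound can favour lists of brighter genes. Ribosome biogenesis, at a median level of 8.76, had 7 of 12 called without the bound and 0 with it.

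**Figure D3:**
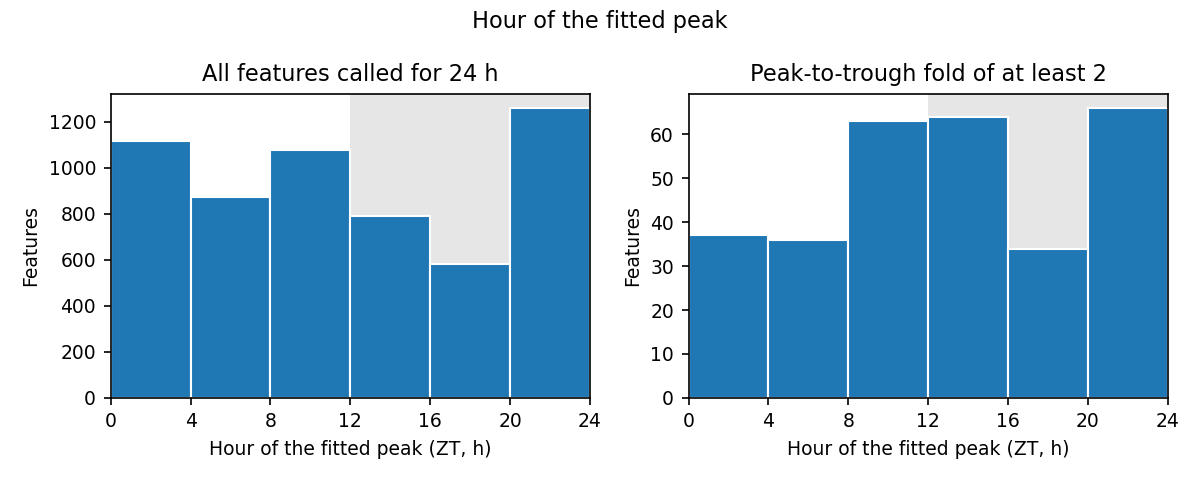
Number of features by hour of the fitted peak in 4-hour bins of Zeitgeber time, for all features called for a 24-hour rhythm and for those with at least a 2-fold difference between peak and trough; grey marks the dark phase. The bin from hour 20 to 24 is the fullest in both, with 1260 and 66 features.

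Cish and Socs2 differed between time points and were not called for a 24-hour rhythm over both cycles. Their levels rose from ZT04 to ZT12 and fell from ZT28 to ZT36. Cish, a cytokine-induced inhibitor, stood at 8.48 ± 0.04 (SD, n = 3) at ZT04 and 11.81 ± 0.14 at ZT12 in the first cycle, and at 11.09 ± 0.14 at ZT28 and 9.47 ± 0.1 at ZT36 in the second (adjusted p = 8.87e-14). Socs2, an inhibitor of growth hormone signalling, likewise went from 9.26 ± 0.05 at ZT04 to 11.68 ± 0.07 at ZT12, and from 10.9 ± 0.1 at ZT28 to 9.98 ± 0.16 at ZT36. Neither passed the test of a wave that differs between the cycles, where Chrna4 was the 1 named gene called. Each time point is 1 set of arrays, and the p-values measure only the spread between arrays. A difference between the samples of single time points therefore cannot be told apart from a course over time. In the second cycle alone 2 of the 4 measured genes of the insulin and growth hormone list were called for a 24-hour rhythm. Igfals was not, so Cish, Socs2 or both were. The kinase Sgk1 (adjusted p = 5.2e-08) and the apolipoprotein Apoa4 (adjusted p = 8.92e-07) also changed with time and had no 24-hour rhythm. Sgk1 was highest at ZT04 (11.24 ± 0.15) and Apoa4 at ZT08 (12.47 ± 0.11). A test of any change over the 12 time points called 5775 features (46.1%), 1661 of them named. With the replicate number as a block the count was 9916.

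Cxcl9, Gpcpd1 and Cd74 had the largest 12-hour amplitudes among named genes, and Cxcl9 and Cd74 were high at ZT08 and ZT32. Cxcl9, a chemokine induced by interferon gamma, had a 12-hour amplitude of 0.72 ± 0.12 (adjusted p = 0.000347). Its level was 11.88 ± 0.17 (SD, n = 3) at ZT08 and 12 ± 0.05 at ZT32, while no other time point exceeded 10.01. Cd74, the invariant chain of class II molecules, stood at 11.75 ± 0.04 and 12.43 ± 0.11 at those hours and at no more than 10.41 elsewhere. H2-Ab1, a class II chain, had levels of 11.06 ± 0.54 and 11.8 ± 0.47 and an adjusted p of 0.033, and 9 of the 36 single arrays end this call when left out, as do replicates 2 and 3 alone (adjusted p = 0.102). Serpina3g, whose probes may bind other members of its family, and Lyz2 were also highest at ZT32. Gpcpd1 (0.64 ± 0.08) and Coq10b (0.55 ± 0.07) added a 12-hour component to their 24-hour wave, both with a 12-hour peak near hour 10. Neat1, a long non-coding RNA, had an amplitude of 0.49 ± 0.06 with a peak at hour 4.4. Socs2 (0.55 ± 0.13) and the acute phase gene Saa1 (0.49 ± 0.11), whose probe may bind Saa2, passed as well. The 12-hour peak of Socs2 lay at hour 10.8 in the first cycle and 8.62 in the second, and Socs2 did not pass with replicates 2 and 3 (adjusted p = 0.1) or with array weights (amplitude 0.35, adjusted p = 0.0544).

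**Figure D4:**
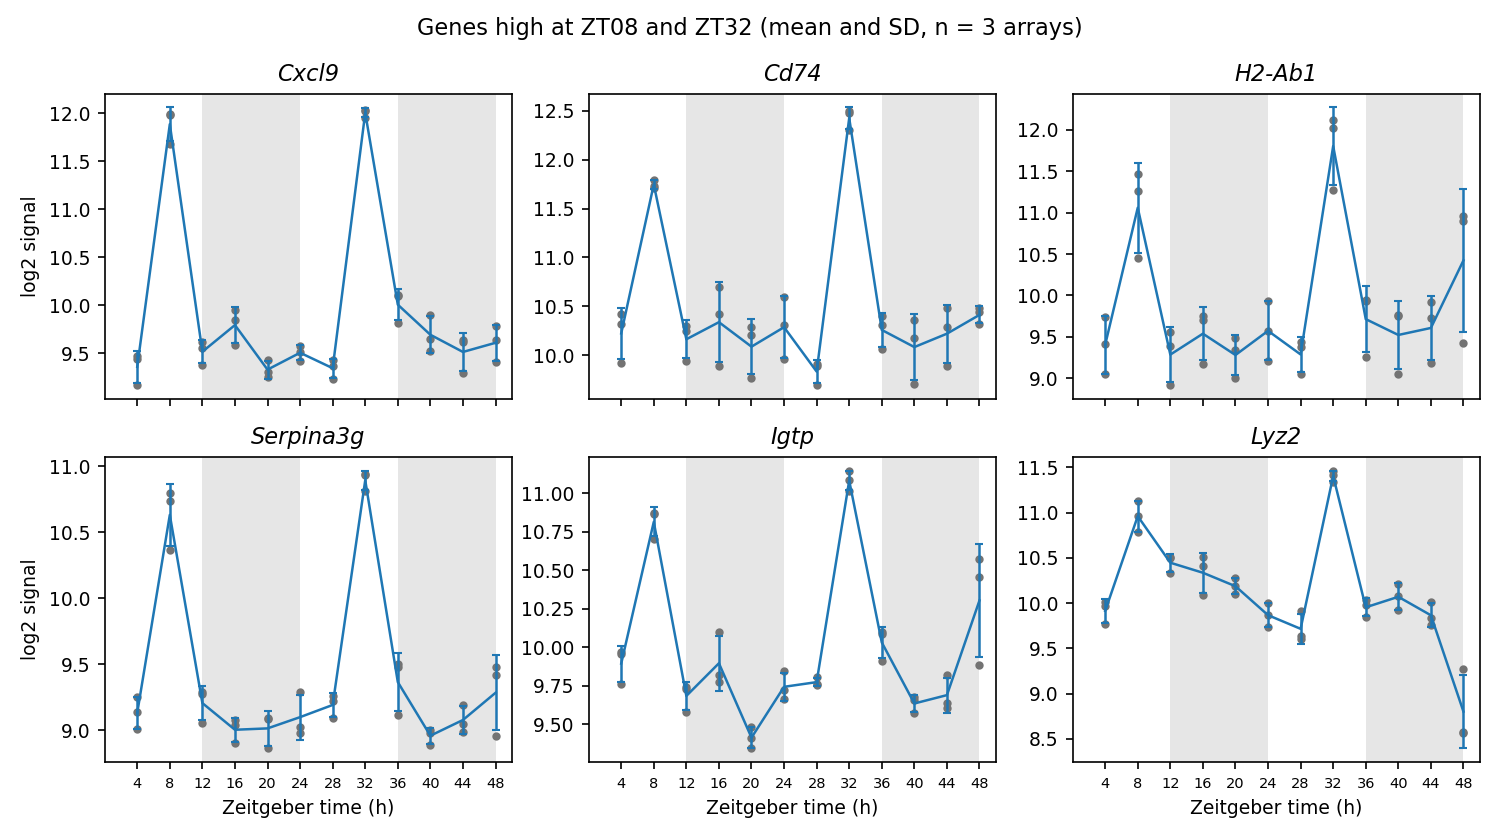
Log2 signal of 6 genes against Zeitgeber time in hours, with single arrays as points, means of 3 arrays joined by lines, SD as bars and the dark phase in grey. All 6 are highest at ZT08 and ZT32, Cxcl9 at 11.88 and 12, and Igtp and Lyz2 were chosen for the plot after their values were seen. H2-Ab1 and Igtp are also raised at ZT48 in replicates 2 and 3.

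The 12-hour component was called in 1241 features (9.9%), 375 of them named genes, and 954 also had a 24-hour rhythm. The median fold of called features was 1.19 and 151 reached 1.5-fold. With the replicate number as a block 2619 were called. On time-point means 4 were called by limma, against 1266 at an unadjusted p under 0.05, and none of the 10 genes of largest 12-hour amplitude was among the 4, the lowest adjusted p being 0.0622 for Coq10b. Without the 3 arrays of ZT24 the count was 2478 and without those of ZT04 it was 788.

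Arrdc3, Gpcpd1 and Mt1 were the named genes most raised in the light phase, and heat shock chaperones and fatty acid synthesis genes were lower. Arrdc3 was higher in the light phase by 1.92 ± 0.1, Gpcpd1 by 1.79 ± 0.07 and Mt1 by 1.67 ± 0.14. Irgm2, an interferon-induced GTPase with close paralogs, was higher by 1.23 ± 0.04, Cxcl9 by 1.06 ± 0.06 and Serpina3g by 0.95 ± 0.06. Outside ZT08 and ZT32 no time point exceeded 10.01 for Cxcl9 or 9.37 for Serpina3g. The differences of these 2 genes therefore rest on ZT08 and ZT32 and do not run through the light phase. Others were the phospholipase Pla2g12a (1.16 ± 0.04), Pik3ap1, an adaptor of phosphoinositide 3-kinase (1.01 ± 0.04), the zinc finger gene Zkscan17 (1.01 ± 0.09) and the sorting receptor Sort1 (0.98 ± 0.05). Ppp1r3b had the largest difference of a named gene in the other direction, with light minus dark of -2.49 ± 0.09. Also lower were Eif4ebp3 (-1.91 ± 0.1), Hspb1 (-1.56 ± 0.12), Hsp90aa1 (-1.26 ± 0.41), Lss (-1.21 ± 0.16) and Elovl6 (-1.19 ± 0.06). Nat8, an acetyltransferase of liver and kidney (-1.15 ± 0.04), Homer2, a scaffold protein (-1.13 ± 0.05), and the actin-associated Palld (-1.1 ± 0.06) were lower too. Of these genes Hsp90aa1 had the highest adjusted p (0.0201), and it was 0.0529 with median scaling. All passed on time-point means.

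By list, 7 of 9 heat shock chaperones fell in the light phase and 0 rose, 7 adjusted over the list alone, with a median difference of -0.59. In fatty acid and triglyceride synthesis 6 of 7 fell (median -0.47), among them Acly (-0.82 ± 0.05) and Fasn (-1.07 ± 0.2). Cholesterol synthesis had 7 members that fell, such as Fdps (-0.46 ± 0.04), and 2 that rose, Hmgcs1 (0.23 ± 0.04) and Nsdhl (0.16 ± 0.04), and 8 fell and 3 rose adjusted over the list alone. In ribosome biogenesis 7 of 12 fell by small amounts, such as Pes1 (-0.19 ± 0.03). The median level of this list, 8.76, lay near the floor, so these amounts may be understated. Of the activator arm 2 of 4 fell, Clock (-0.41 ± 0.04) among them, and of the genes downstream of the clock Por (-0.69 ± 0.06) and Cyp2a5 (-0.43 ± 0.05) fell. Sqstm1 (0.35 ± 0.04) and Lamp2 (0.24 ± 0.06) of the autophagy list and Klf6 (0.32 ± 0.06) and Junb (0.22 ± 0.04) of the immediate early list rose. Camera found 5 lists lower in the light phase than other genes, at adjusted p of 2.27e-06 for heat shock chaperones, 8.16e-06 for fatty acid synthesis, 0.0185 for ribosome biogenesis, 0.025 for the activator arm and 0.00515 for genes downstream of the clock. With an estimated correlation 3 held, heat shock chaperones (adjusted p = 0.0012), fatty acid synthesis (adjusted p = 0.0117) and ribosome biogenesis (adjusted p = 0.038). The activator arm had an adjusted p = 0.261 with an estimated correlation and the genes downstream of the clock an adjusted p = 0.0557 with an estimated correlation. With the replicate block the preset camera call of the activator arm ended (adjusted p = 0.051), and that of cholesterol synthesis, 0.0586 without the block, passed (adjusted p = 0.0238). With the block and an estimated correlation the genes downstream of the clock (adjusted p = 0.0474) and cholesterol synthesis (adjusted p = 0.0449, against 0.38 without the block) passed beside these 3. Fry, which asks only whether a list moves on balance, called 17 lists.

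In all 3610 features differed between light and dark phase, 1988 higher and 1622 lower in the light, 566 and 496 of them named genes. Of these features 99.2% had the same sign in both cycles, which selection with both cycles favours. Among the called features, 26 of the higher and 38 of the lower differed by at least 2-fold. With the replicate block 5958 features were called and on time-point means 1748. The split depends on the scaling, with 3423 higher and 702 lower under median scaling and 2563 higher and 916 lower in the authors' table. The median light minus dark over all features was 0.000626 in the main fit, 0.0361 under median scaling and 0.0939 in the authors' table.

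Mt1, Acss2 and some genes of sterol and fatty acid synthesis were higher in the second cycle than in the first. Mt1 was higher by 0.65 ± 0.14, Acss2, which activates acetate, by 0.45 ± 0.06, Hmgcs1 by 0.36 ± 0.04, Nsdhl, a sterol dehydrogenase, by 0.34 ± 0.04 and Acly by 0.32 ± 0.06. Of 15 genes of cholesterol synthesis 4 rose and 0 fell, Fdps (0.28 ± 0.04) and Acat2 (0.29 ± 0.06) being the others. Of the 3 probes of Nsdhl the brightest gave this value and the others 0.04 and 0.06, so Nsdhl is uncertain. Of 7 of fatty acid synthesis Acly and Acaca (0.2 ± 0.05) rose. The histone genes H2bc13 (-0.6 ± 0.16), H2bc15 (-0.48 ± 0.13), H2bc11 (-0.43 ± 0.1) and H2bc14 (-0.41 ± 0.11) were lower, and so was Eif4ebp3 (-0.43 ± 0.09). These histone genes are near-identical and their probes may bind several of them, so the 4 values are uncertain. The arrays of ZT48 stood apart, mainly those of replicates 2 and 3, with 3364 features different between ZT48 and ZT24 against 63 to 207 for the other pairs of the same hour. Without ZT48 Acss2, Hmgcs1, Nsdhl and Acly kept their calls, and 4 genes lost theirs. Of these Mt1 (0.62, adjusted p = 0.0569) and Eif4ebp3 (-0.39, adjusted p = 0.058) kept most of their difference, and H2bc13 (-0.33, adjusted p = 0.205) and H2bc14 (-0.21, adjusted p = 0.0785) had smaller ones. H2bc13, H2bc14, H2bc15 and H2bc11 did not pass in the authors' table either (adjusted p from 0.086 to 0.192).

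The comparison called 195 features, 115 higher and 80 lower in the second cycle, 67 of them named genes. With the replicate block 1527 were called. On time-point means limma called 0, with 1192 at an unadjusted p under 0.05. Without ZT48 68 were called, 49 of them among the 195. The count also depended on single arrays, at 123 without ZT16 replicate 1, 113 without ZT24 replicate 1, 114 without ZT24 replicate 3, 113 without ZT48 replicate 2 and 121 without ZT48 replicate 3. The split was 34 higher and 147 lower with median scaling, and 194 higher and 50 lower in the authors' table.

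The 24-hour wave itself differed between the cycles in 5 features, Chrna4, a subunit of the nicotinic acetylcholine receptor, and 4 unnamed probes. The amplitude of Chrna4 was 0.19 in the first cycle and 0.56 in the second, with peaks at hours 17.8 and 18.5 and levels of 8.81 ± 0.04 (SD, n = 3) at ZT16 and 9.36 ± 0.04 at ZT40 (adjusted p = 0.0427). With the replicate block the count was 9. Chrna4 did not pass under median scaling (adjusted p = 0.457), cyclic loess (adjusted p = 0.227) or in the authors' table (adjusted p = 1). On time-point means limma called 0 features, with 122 at an unadjusted p under 0.05. Of the 36 arrays, 24 ended the call of Chrna4 when left out alone. The count was 2 without any of the 3 arrays of ZT08 or ZT20, ZT24 replicate 3, ZT32 replicate 3 or ZT36 replicate 2. It was 3 without ZT04 replicate 1 or 3, ZT12 replicate 2, ZT24 replicate 1 or 2, ZT28 replicate 2 or 3, ZT40 replicate 2 or 3 or ZT48 replicate 3, 10 without ZT44 replicate 1 and 9 without ZT48 replicate 1.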

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

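The 2 tests of the 12-hour component, that of a change of the second cycle alike at every hour and the reading of arrays of neighbouring hours were chosen only after the result was seen. The time labels were first shuffled within each replicate number, in 100 assignments, and 1 assignment, the real one, called as many features for each result. The real count and the highest other were 5694 and 0 for the 24-hour rhythm, 5775 and 35 for any change with time, 1241 and 0 for the 12-hour component, 3610 and 3 for light against dark, 195 and 1 for second against first cycle and 5 and 0 for the rhythm by cycle. This excludes that the arrays carry no time signal at all. The shuffle breaks up every time point and with it the 24-hour rhythm, so it does not judge the smaller counts apart from any change with time.

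Whole time points were also shuffled, which is strict because real 24-hour genes move along. For the 24-hour rhythm 1 of 100 orders called as many features (real 5694, highest other 3426), so chance can be excluded. For light against dark 4 of 100 did (real 3610, highest other 4020), and for second against first cycle 1 of 32 exchanges did (real 195, highest other 119). Both met the bound set before, yet another order called more for light against dark and 1 of 32 is the lowest share possible, so chance is not firmly excluded for them. For the 12-hour component 25 of 100 orders called as many (real 1241, highest other 3059), and for the rhythm by cycle 28 of 32 exchanges did (real 5, highest other 80). Chance cannot be excluded for these 2 results. For the 12-hour component the shuffle also moves real 24-hour genes, which can raise the counts of other orders, so this test cannot decide. For the rhythm by cycle the exchanges keep the hour of day. Their higher counts may come from time points that differ as a whole, which was not tested.

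The arrays of ZT48 differed from those of ZT24 in 3364 features, 1917 higher and 1447 lower. In replicates 2 and 3 this difference did not follow that of replicate 1 from the others at the other hours (correlation across features -0.0757). The same shift was thus excluded as the source. The test does not cover a source that acted mainly on replicates 2 and 3, where the SD of the difference was 0.447 against 0.169 in replicate 1. A change of the second cycle alike at every hour was excluded as the whole source, since the other pairs of the same hour called 63 to 207 features, at most 6.15% of the 3364. A part shared with the rest of the second cycle stayed open, as the correlation of 0.191 was under the bound of 0.2 set for excluding it but the rule was then changed to the range on leaving out each pair (0.138 to 0.244). A sample taken at another hour stayed open too, since the hour read from the 24-hour genes lay within 0.293 hours of 24 on all 3 arrays, under the bound of 4 set before, but the arrays of ZT04 read hours 0.614 to 0.776 in a fit that also left out ZT24 and ZT48, so that bound was too wide. No biological explanation was tested.

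Replicate 1 stood apart from replicates 2 and 3. The choice among the normalizations used was excluded as the source, as the component that separates replicate 1 held at least 31.1% of the variance under the others. No setting without normalization between arrays was run, so an effect common to all of them is not covered. A dependence on signal strength stayed undecided at a rank correlation of -0.175. Of 3 marker lists 0 lay outside the range of random lists, which speaks weakly against another mix of cell types, since each list held 5 genes, and the rule was tightened after a first run without a change of outcome. No other biological explanation was tested, and the labels do not say whether the replicates are separate animals.

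The 12-hour component was nearly lost on time-point means, where 4 features were called. Whether it comes from 24-hour waves that are not sinusoidal stayed open for the called features as a set. The share of its features with a 24-hour rhythm (76.9% against 42% of the others) would be larger under any cause that favours features of low noise. Cxcl9 and Cd74 were high only at ZT08 and ZT32, with no other time point above 10.01 and 10.41. Their 12-hour terms therefore do not stand for a second daily peak. Time points that stood apart once stayed undecided as well. Of features called in the first cycle alone 54.5% had a 12-hour peak within 1.5 hours in the second, and 59.3% in the reverse direction, where chance gives 25%. A first version of this test used features called over both cycles and gave 78.7% (27% of those not called), which by its bound would have counted against time points that stood apart once, and it was replaced because its features had been selected with both cycles.

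A difference between the 2 cycles singled out 5 features, whose 24-hour wave differed by 1.96 for the unnamed probe scl48625.8_280-S, 0.72 for a RIKEN clone probe (D630035N04), 0.55 for GI_38081206-S, 0.44 for scl50427.9.1_25-S and 0.37 for Chrna4. The wave of the largest had an amplitude of 0.71 with a peak at hour 5.02 in the first cycle and of 1.25 with a peak at hour 17 in the second. As given above, 28 of 32 exchanges called as many features.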

How the results depend on the processing

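Tests chosen only after the result was seen were the time-point means, the fits without ZT48, replicate 1 alone and replicates 2 and 3 alone. Median scaling and the authors' values shifted the features as a whole, as given below for the peak hours. Beyond that shift, why a value moved was not tested for any of those below.

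The 24-hour rhythm (5694) was called in 8590 features with array weights, 2977 in the first cycle, 3198 in the second, 971 with a fold of at least 1.5, 3311 on time-point means and 3373 with replicate 1. Any change with time (5775) was called in 9916 with the block, 10649 with weights and 8906 with replicates 2 and 3.

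The 12-hour component (1241) was called in 720 with median scaling, 776 with the authors' values, 2619 with the block, 5688 with weights, 576 at an adjusted p under 0.01, 151 with a fold of at least 1.5, 4 on time-point means, 2748 with the block without ZT48 and 29 with replicate 1. Light against dark (3610) was called in 5958 with the block, 5896 with weights, 1927 in the first cycle, 1748 on time-point means, 6594 with the block without ZT48 and 1915 with replicate 1.

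Second against first cycle (195) was called in 105 without a filter, 1527 with the block, 1429 with weights, 47 at an adjusted p under 0.01, 0 on time-point means (limma, 1192 at unadjusted p under 0.05), 68 without ZT48, 962 with the block without ZT48 and 406 with replicates 2 and 3. The rhythm by cycle (5) was called in 8 without background correction, 1 with median scaling, 1 with the authors' values, 2 without a filter, 9 with the block, 83 with weights, 1 at an adjusted p under 0.01 and by limma in 0 on time-point means, 0 with replicate 1 and 0 with replicates 2 and 3.

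Of called features 53.8% peaked between hours 0 and 12, and 77.9% with median scaling, 55.4% with cyclic loess, 69.3% with the authors' values, 55.5% without a filter, 52.1% with detection on all 36 arrays, 53.2% with the block, 53.5% with weights, 54.1% in the first cycle, 52% in the second, 49.2% with a fold of at least 1.5, 52.6% by ranks, 52.2% on time-point means, 52.8% with the block without ZT48 and 51.1% with replicate 1. Over all features, called or not, the share was 50.5% in the main fit, 74% with median scaling and 65.9% with the authors' values. Lists called by Fisher's test (0) were 2 without a filter, 1 in the second cycle and 5 with a fold of at least 1.5. Camera (5) called 10 with median scaling, 11 with the authors' values, 10 without a filter and 3 at an adjusted p under 0.01, and fry (17) called 11 with median scaling, 6 on time-point means and 5 with replicate 1. The peak of Cox8a was reversed in the authors' values (amplitude 0.0718, adjusted p = 0.498, hour 16.6, against hour 0.462).

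Leaving out 1 array at a time gave 5463 to 5859 for the 24-hour rhythm, 4778 to 6801 for any change, 1070 to 1396 for 12 hours, 3409 to 4102 for light against dark, 113 to 240 for the cycles, 2 to 10 for the rhythm by cycle, 52.4% to 54.9% for peaks, 0 to 0 lists by Fisher's test, 5 to 6 by camera and 15 to 18 by fry. The slide block was not run, and replicate 1 alone and time-point means give no test of any change. Array weights did not converge and ran from 0.06 (ZT48 replicate 1) to 48.7 (ZT44 replicate 2), so their counts carry little weight. Without background correction signals hold the background, and with it the floor limits dim genes.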

Other observations

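The tests of the interferon list were written after 5 immune genes had been seen high at hour 8, and those genes are not in the list tested. Hour 8 had the most features above all other time points in both cycles. At hour 8, 5 features lay at least 2-fold above all other time points, against 1 at hour 12 and 0 at each other hour. With at least 1.5-fold there were 13 at hour 8 and up to 3 at the others, while 6 lay at least 1.5-fold below all others at hour 12 and 5 at hour 8. In single time points 58 features were at least 2-fold higher than the mean of the others at ZT32, 42 at ZT12, 41 at ZT48 and 38 at ZT08. Cxcl9 was 5.18-fold above the mean of other time points, Cd74 3.72-fold, H2-Ab1 3.65-fold, Serpina3g 3.09-fold, Dedd2, which has a death effector domain, 2.49-fold, and Ear1, an eosinophil ribonuclease, 2.43-fold.

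This may be an interferon gamma response. Of 37 listed genes 14 were tested, and their median difference of 0.22 lay above 100% of 10000 random lists, with 9 higher and 0 lower. Igtp (1.14), Psmb10 (0.47), H2-DMa (0.35), Irf1 (0.34) and Cd274 (0.18) were among them, and Socs1, H2-K1, Psme1, Psme2 and Ifi47 did not pass. Of a type I list of 14 genes 4 were tested, with a median of 0.12 above 99.9% of random lists, so the 2 responses cannot be told apart, and random lists ignore that such genes move together. The median was 0.16 at ZT08, 0.34 at ZT32 and at most 0.01 elsewhere. At ZT48 it was -0.05, with 6 of 14 members higher. Single genes were raised there in replicates 2 and 3, Igtp at 10.45 and 10.57 (9.88 in replicate 1). H2-Ab1, outside the list tested, stood at 10.95 and 10.89 (9.42 in replicate 1).

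Another explanation is an event confined to the samples of single time points, since each time point is 1 set of arrays. If 2 time points were struck at random they would share an hour of the day in 9.09% of cases, so this cannot be excluded by the 100% of random lists above. The macrophage markers Lyz2 (10.96 ± 0.17, SD, n = 3, and 11.4 ± 0.06) and C1qb (10.99 ± 0.56 and 11.41 ± 0.41) were also highest at ZT08 and ZT32. A change in immune cells was not tested and stays open. An independent series sampled at hour 8 would help to tell these apart.

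The hour of day was read from each array with genes fitted at the other hours. Over 36 arrays the median difference from the label was 0.735 hours, the largest 3.81 hours, and 33 lay within 2 hours. The 3 others were the 3 arrays of ZT04, which read hours 0.189 to 0.626, while the arrays of ZT28 read hours 2.85 to 2.89.

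Genes that set ZT48 apart from ZT24 included Mylk, a myosin kinase (1.93 ± 0.26), and the chemokine Cxcl1 (1.61 ± 0.17), both higher, and the carriers Mtch2 (-2.96 ± 0.43) and Scp2 (-2.75 ± 0.58), both lower. The arrays of ZT48 were split in Mtch2 (SD 1.83, n = 3, against 0.03 at ZT24), Scp2 (SD 2.22 against 0.3) and Mylk (SD 1.03 against 0.21). Camera found the endothelial list different at an adjusted p of 0.0401, and at adjusted p = 0.519 with an estimated correlation. At ZT48 the SD of the difference from ZT24 was 0.447 in replicates 2 and 3 and 0.169 in replicate 1. At the other pairs of the same hour it was 0.118 to 0.163 in replicates 2 and 3 and 0.138 to 0.168 in replicate 1.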
